A study of Mus musculus with 4 samples.

How the data were processed

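The samples were CD45+ immune cells from the cortex of 18-month-old mice, profiled by single-cell RNA sequencing. APP/PS1 mice, a transgenic line that deposits amyloid, are called AD here, and APP/PS1 mice that also lack the receptor tyrosine kinases Axl and Mertk, per the labels, are called ADAM. Per the labels, each of the 4 libraries (AD 1, AD 2, ADAM 1 and ADAM 2) pooled 2 cortices, and each genotype had 2 biological replicates. The tissue was digested with enzymes and broken up mechanically, debris was taken out on Percoll, and CD45+ cells were sorted, per the labels' protocols. The libraries were made with 10x Genomics 3′ chemistry, which counts molecules by unique molecular identifiers (UMIs) read near the 3′ end of a transcript.

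The deposited table holds the authors' raw UMI counts for 16798 genes, named by symbol, in 15451 cells, with no normalization. A table of cells, made by the authors, gives the library, a cell class, a numbered microglia state, UMI and gene counts, the mitochondrial share and doublet marks of each cell. The submitters' processing notes name Cell Ranger 3.1.0, Seurat 3.2.1.9002 and mm10 without saying which step each served. In all 15451 cells the authors' UMI and gene counts equalled those of the count table. The mitochondrial percent deposited by the authors equalled the share of UMIs on 13 mitochondrial genes. The lowest UMI count of a deposited cell was 500, the lowest gene number 207 and the highest mitochondrial share 9.99%, and the filters themselves are not given in the sources used here. The authors marked 823 cells as doublets, which carry no class, and 216 cells of the microglia class as microglia and T cell doublets, which carry no state. How the doublet score deposited by the authors was made is not given in the sources used here, and the score was not used. Among the cells, 14628 had 1 of 9 classes, 9293 were of the microglia class and 9077 of these had 1 of 7 states.

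Raw UMI counts were summed per library over the cells of each class and each microglia state, and libraries, not cells, were the replicates. Microglia here are the 9077 cells with a state. Sets with at least 20 cells in each library were tested between the genotypes with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. The test used TMM scaling, the expression filter of edgeR with a minimum count of 10, a robust fit, genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Levels are CPM (counts scaled to library size, after TMM scaling), given as mean ± SD of 2 libraries, log2 folds are ADAM over AD, and standard errors (SE) come from the fold and the F statistic. Sums over cell type markers, haemoglobin genes and S100a8 and S100a9 are CPM without TMM scaling. The same holds for the per-library values of Ddx3y, of Saa3, of Axl over all cells and of Mertk given in the text for T and NK cells. A fold against a group with 1 to 3 UMIs is given as a ratio with an exact 95% counting interval. A fold against a group without UMIs is given as a lower bound at 3 UMIs over the group. Intervals and bounds cover counting error only. State 5 and state 0 were compared within libraries by edgeR with library as a term, in each genotype, over both, and as a state by genotype interaction.

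Before the data were examined, the gene lists, the cell type markers, the tests and most alternatives were fixed, as was the rule for naming genes. The rule took, for microglia, the TAM receptors and ligands, up to 10 called genes per direction with a mean log2 CPM of at least 3 and no overlap of the libraries, and members of each list. Predicted genes and ribosomal protein genes were left out of it, and other sets had up to 4 genes per direction and up to 2 members of each called list. Genes named outside this rule are said to be chosen after their values were seen. The 15 lists were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, with Axl and Mertk removed. The same test with an estimated correlation, and fry, were the alternatives. Median folds of a list are over its tested members. Numbers of cells per class and per state were tested with edgeR, with the total cells as library size. An exact permutation test of 2 against 2 libraries has 6 arrangements and cannot go below a two-sided p of 0.333.

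To compare shares of cells with a UMI across depths, microglia were thinned to 2000 UMIs each. This left out 164, 186, 247 and 258 microglia of AD 1, AD 2, ADAM 1 and ADAM 2 and kept 1436, 2914, 2070 and 1802. Gene positions are those of GENCODE vM21 on GRCm38 (mm10), in which 16580 of the gene names matched exactly once. Genes within 20 Mb of Axl or Mertk were compared with all other tested genes by Fisher's exact test. Scrublet marked 74, 78, 6 and 49 cells in AD 1, AD 2, ADAM 1 and ADAM 2. The share in ADAM 1 was only 0.168%, and whether the caller worked there was not tested, so the authors' doublet marks were used. Other software was DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9.

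The tests were tried on simulated counts drawn from the means and library sizes of the real genes, with 200 genes changed by 2-fold or 4-fold in each comparison. Among 11924 simulated microglia genes, 49% of the 2-fold and 86% of the 4-fold changes were recovered, and 6.90% of calls were false. The recovered shares of 4-fold changes were 94% in state 0, 91% in state 5, 94% in T and NK cells, 57% in macrophages and 83% in the interaction. In monocytes 45% of the 4-fold and 0% of the 2-fold changes were recovered, with 15.1% of calls false, and in proliferating cells 0% of either. The simulated spread was more even across genes than the real one in all sets but state 3, with a prior df of 10.3 against 6.11 in microglia, so these shares may be optimistic. A planted list was called in 8 of 10 simulated comparisons by camera at 0.01 and in 0 of 10 with an estimated correlation. The simulated genes were drawn independently, so this does not show how either form behaves on correlated genes, and false calls of lists are not given. In real monocytes with under 1% of UMIs from neutrophil markers, estimated correlations ran from −0.17 (T cell activation) to 0.56 (MHC class II).

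Alternatives covered other size factors, filters, tools, cell selections, replicate block, gene exclusions, own Leiden clustering and leaving out each library in turn, and 8 more were added after seeing the data. Where a library is left out, the lone library of its genotype is assumed to vary like the others. B cells, neutrophils, endothelial cells, oligodendrocytes, state 1 and state 6 had under 20 cells in a library and were not tested for genes. In the closing tests that set a median against a bound, a median had to lie beyond it by the larger of 2 bootstrap SE (10000 draws over genes, which are not independent) and the SD of the values without each library. The first form of this rule was set after the medians were seen, and the SD was added after the result for ADAM 2 in the state 5 and state 0 comparison was known, which moved that result from excluded to undecided. The test of the border between the states was counted as undecided because under 10% of cells changed sides, a rule set after its result was known, which moved it from excluded to undecided. The test of loss of function by gene position replaced an earlier one after its odds ratio was known. On the called genes, it and the test of linked sequence were then counted as undecided, since both count the genes that make up the pattern. The ratio over genes at an unadjusted p under 0.05, known by then, was read for loss of function alone.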

Results

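Single-cell RNA profiles were collected from CD45+ cells of aged cortices of AD mice and of ADAM mice, in 2 libraries per genotype. AD 1 held 3241 cells and 14963857 UMIs, AD 2 4543 cells and 29831947 UMIs, ADAM 1 3578 cells and 23190134 UMIs, and ADAM 2 4089 cells and 26212313 UMIs. The median depth per cell was 3704, 5457, 5164 and 4953 UMIs in the same order. The authors' classes were microglia, T and NK cells, monocytes, macrophages, proliferating cells, neutrophils, B cells, endothelial cells and oligodendrocytes. Microglia with a state numbered 1600, 3100, 2317 and 2060, with 8580653 to 21704070 UMIs per library. The male gene Ddx3y stood at 62.0, 67.9, 55.9 and 53.4 CPM in the microglia of AD 1, AD 2, ADAM 1 and ADAM 2. Replicate libraries of 1 genotype differed beyond sampling noise, with a chi-square per degree of freedom over microglial genes of 20.1 in AD and 28.6 in ADAM. Adjusted p-values of the gene tests below are from edgeR unless another tool is named, and they measure the spread between pools of cortices.

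The first question was whether the deleted receptors were lost in the libraries labelled ADAM. Axl, a TAM receptor that binds phosphatidylserine through its ligands (chromosome 7, 25757273 to 25788705), was far lower in both ADAM libraries. Over all cells with a class it stood at 72.7 CPM in AD 1, 58.1 in AD 2, 5.23 in ADAM 1 and 5.28 in ADAM 2. In microglia it was 84.3 ± 27.1 CPM in AD and 6.46 ± 1.53 in ADAM, a log2 fold of −3.70 (SE 0.32). Axl also fell within state 0 (log2 fold −3.39), state 5 (−3.87), state 4 (−3.75) and macrophages (−3.18), with edgeR adjusted p of 2.0e-06, 2.4e-09, 4.0e-05 and 0.0066. In state 3 the AD level was 19.7-fold the ADAM level (counting interval 4.98 to 170, edgeR adjusted p = 0.0023). The edgeR adjusted p over all microglia was 0.195, while DESeq2 gave 2.5e-37 and limma-voom 0.022. In monocytes and state 2 the Axl folds of −3.49 and −3.25 had edgeR adjusted p of 0.14 and 0.249.

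At least 1 Axl UMI was found in 27.8% of AD 1 microglia (exact 95% interval 25.6 to 30.1), 24.5% of AD 2 (23.01 to 26.1), 3.11% of ADAM 1 (2.44 to 3.90) and 4.17% of ADAM 2 (3.35 to 5.13). In T and NK cells, which should lack it, the shares were 1.17%, 1.69%, 1.03% and 0.543%. Median depths were 4719.5, 6170, 5472 and 5698.5 UMIs in microglia and 2925.5, 3547.5, 3406 and 3416 in T and NK cells. After thinning, the microglial shares were 13.6%, 9.61%, 0.773% and 1.44%. Mertk, the phagocytic TAM receptor of resting microglia (chromosome 2, 128698956 to 128802894), differed in CPM by less than the spread between replicates. Its microglial level was 280 ± 10.3 CPM in AD and 266 ± 28.8 in ADAM, a log2 fold of −0.075 (SE 0.13, edgeR adjusted p = 1.0), and +0.030 without ADAM 1. The share of microglia with a Mertk UMI was 64.1%, 74.7%, 60.3% and 61.0% in AD 1, AD 2, ADAM 1 and ADAM 2, and 40.7%, 42.6%, 34.0% and 37.8% after thinning, lower in both ADAM libraries, a difference that an exact permutation test cannot call with 2 libraries per genotype. In T and NK cells it was 0.881%, 1.45%, 3.39% and 3.39%. A 3′ tag outside the deleted part checks nothing about the label, and which part of Mertk was deleted is not given in the sources used here. The TAM ligands Gas6 and Pros1 had log2 folds of +0.095 (SE 0.12) and +0.050 (SE 0.12), neither past the test, and the third receptor Tyro3 had at most 1 UMI in the microglia of any library.

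**Figure D1:**
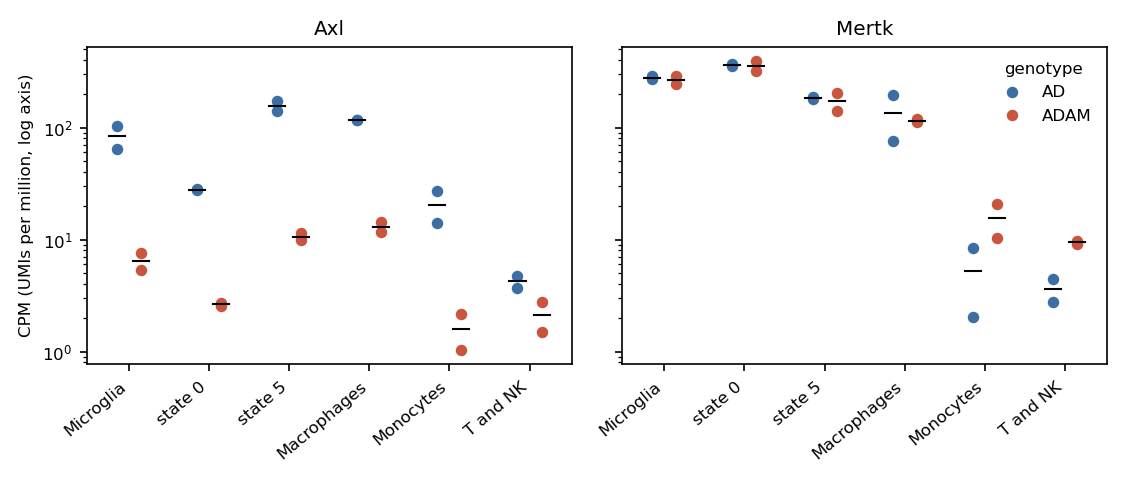
Axl and Mertk level (CPM, log axis) per library in microglia, states 0 and 5, macrophages, monocytes and T and NK cells, with points for libraries and lines for means. Axl in microglia lies at 65.1 CPM or above in AD and at 7.54 or below in ADAM, whereas the Mertk points of the genotypes overlap in microglia.

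The genotypes were then compared across microglia as a whole. The genes Spint1, Kcnip3 and Eif3j1 were lower in ADAM microglia and Gatm and Eif3j2 were higher, 5 of 11924 genes tested, with 280 at an unadjusted p under 0.05. These 280 are below the share of 0.05 of the tested genes that falls under this limit when no gene differs. The counts below lie under that share in macrophages and states 0, 2, 3 and 4. They lie above it in monocytes, proliferating cells, T and NK cells and state 5. Spint1, a serine protease inhibitor (chromosome 2, 119237362 to 119249527), fell from 91.2 ± 1.55 CPM to 3 UMIs in both ADAM libraries together, 867-fold (counting interval 296 to 4205, edgeR adjusted p = 2.0e-04). Gatm, which makes the precursor of creatine (chromosome 2, 122594467 to 122611303), rose from 102 ± 14.6 to 812 ± 152 CPM, a log2 fold of 2.99 (SE 0.18, edgeR adjusted p = 6.9e-04). Eif3j1, a subunit of a translation initiation factor (chromosome 2, 122028546 to 122056598), fell from 115 ± 11.9 to 27.9 ± 5.54 CPM (log2 fold −2.04, SE 0.16, edgeR adjusted p = 0.0052). Its copy Eif3j2 (chromosome 18, 43475418 to 43477796) rose from 1.98 ± 0.97 to 40.5 ± 6.48 CPM (log2 fold 4.52, SE 0.30, edgeR adjusted p = 0.011). Reads can be shared between these copies, so both values are uncertain. Kcnip3, a calcium-binding protein (chromosome 2, 127456498 to 127522094), chosen after its values were seen, fell from 9.67 ± 0.04 CPM, 137-fold (counting interval 37.7 to 1139, edgeR adjusted p = 4.4e-04). DESeq2 called 17 genes and limma-voom 6. Without AD 1, AD 2, ADAM 1 or ADAM 2, edgeR called 12, 27, 139 and 29, of which 7, 11, 114 and 18 were higher.

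By list, interferon response genes stood higher in ADAM microglia, with positive folds in 27 of 30 members and a median log2 fold of 0.23 (camera adjusted p = 4.1e-14). Cxcl10, an interferon-induced chemokine, was at 20.8 ± 3.02 CPM in AD and 43.7 ± 2.91 in ADAM (log2 1.05, SE 0.13, edgeR adjusted p = 0.0656), and Ifitm3, an antiviral membrane protein, at 113 ± 21.1 and 202 ± 33.0. No member passed over all genes, and 2 were higher adjusted over the list alone. The inflammatory cytokine and NF-kB list had a median of 0.25, with 21 of 25 positive and 1 member higher adjusted over the list alone (camera adjusted p = 1.8e-04), among them the chemokine Ccl12 at 191 ± 4.95 and 407 ± 124 CPM. Glycolysis and hypoxia (median 0.21, 18 of 20 positive, camera adjusted p = 3.2e-04), proliferation (0.21, 18 of 20, camera adjusted p = 0.0016) and dissociation and immediate early genes (0.16, 24 of 29, camera adjusted p = 0.044) also passed camera, with 0 members of each higher adjusted over the list alone. Of the proliferation list, Pcna, the clamp of DNA replication, was lower adjusted over the list alone, with a log2 fold of −1.02 (SE 0.18, edgeR adjusted p = 0.32), and it lies within 20 Mb of Mertk and can share reads with a pseudogene copy. Homeostatic microglia genes had a median of −0.12 and 19 of 20 negative (camera adjusted p = 0.0033), with 0 members lower adjusted over the list alone. Each of these 6 calls was lost with an estimated correlation (adjusted p = 0.986), and fry called 0 lists in either form, with 0 (directional) and 1 (mixed) at an unadjusted p under 0.05.

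Some of these medians rested on single libraries. Without ADAM 2 the inflammatory list stood at −0.047, the immediate early list at −0.081 and the homeostatic list at +0.043. Camera did not pass for homeostatic genes without AD 2 (camera adjusted p = 0.45) or ADAM 2 (0.71), inflammatory genes without ADAM 2 (0.71), proliferation and glycolysis without AD 2 (0.29 and 0.91) or ADAM 1 (0.74 and 0.20), and immediate early genes without AD 1 (0.53) or AD 2 (0.098). In ADAM 2 the neutrophil markers summed to 921 CPM in microglia, against 183, 205 and 184 in AD 1, AD 2 and ADAM 1, and haemoglobin genes to 4498 CPM against at most 0.612. Under a marker rule in place of the authors' annotation, which kept 351, 403, 410 and 21 cells of AD 1, AD 2, ADAM 1 and ADAM 2, the interferon median was −0.086.

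The other lists did not pass in microglia. Disease-associated microglia (DAM) genes had a median log2 fold of 0.0017, with 16 of 31 members positive (camera adjusted p = 0.972). Phagocytosis and complement (0.0058), lysosome (0.025) and T cell activation (0.022) also had medians near 0. MHC class I had a median of 0.083 (camera adjusted p = 0.168), mitochondrially encoded genes 0.17 (0.0818) and cholesterol and lipid handling −0.096 (0.101). MHC class II at −0.12 and the Alzheimer risk and amyloid genes at −0.025 had medians opposite in sign to their tests (camera adjusted p = 0.972 for both), as did the DAM list, and the mean of the T cell activation list was below 0 while its median and test were above.

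Of the called microglial genes, Spint1, Kcnip3, Gatm and Eif3j1 lie on chromosome 2 within 20 Mb of Mertk. Called genes were 4 of 566 tested within 20 Mb of Axl or Mertk and 1 of 11356 elsewhere, an odds ratio of 80.6 (95% interval 7.97 to 3871, Fisher's exact p = 2.4e-05). At an unadjusted p under 0.05 the shares were 8.30% of the near genes and 2.04% of the others (odds ratio 4.34, 3.06 to 6.04, Fisher's exact p = 1.9e-14). All 4 lay near Mertk and 0 near Axl. A window of 5 Mb held 1 called gene, and its odds ratio of 12.7 did not pass (Fisher's exact p = 0.0928). When genes within 20 Mb were left out of the fit, edgeR called 0 genes in microglia, with 230 at an unadjusted p under 0.05. Gatm was called in 8 of the 10 cell sets tested, Eif3j1 and Eif3j2 in 6 each, and Spint1 in 5. In T and NK cells Gatm stood at 3.90 CPM in AD and 31.8 in ADAM, against 102 and 812 in microglia. Those cells of ADAM also held more transcripts of microglial genes, so their Gatm call is not shown to be independent of microglia.

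**Figure D2:**
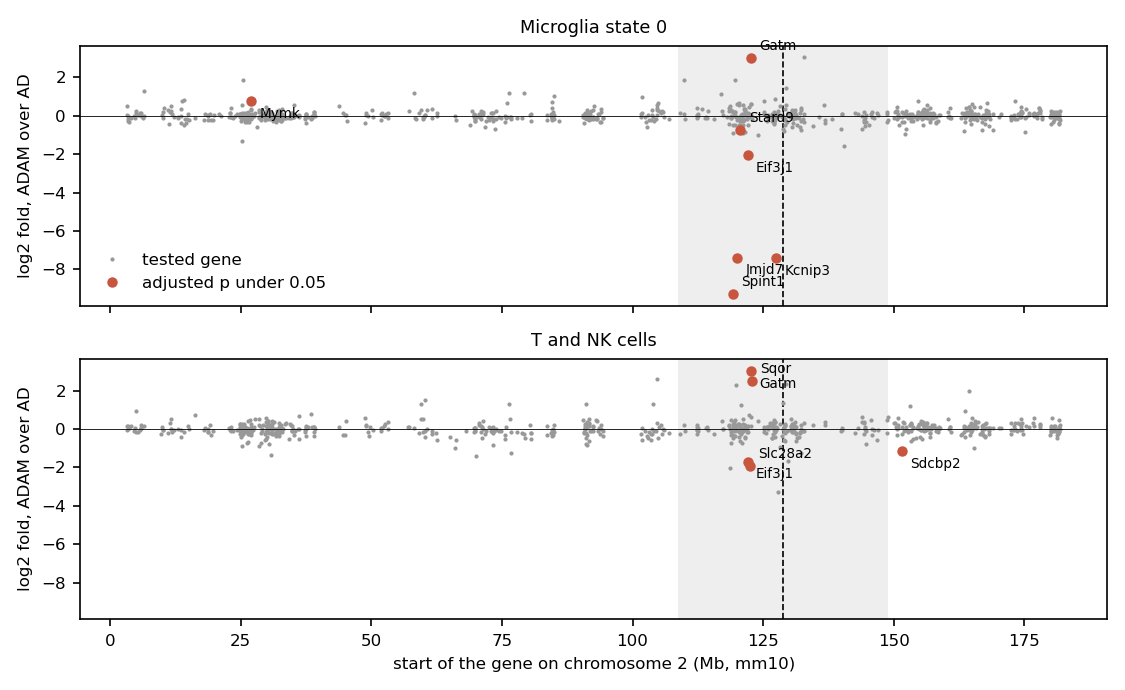
Log2 fold of each tested gene, ADAM over AD, against its start on chromosome 2 (Mb, mm10) in state 0 microglia and in T and NK cells, with called genes named, the 20 Mb on either side of Mertk in grey and Mertk as a dashed line. Gatm lies at 3.01 in both, on the grey background.

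Microglia states were compared next, to see the genotypes within cells of 1 kind. State 0 was led by homeostatic genes such as Tmem119 and P2ry12, and state 5 by DAM genes such as Gpnmb, Cst7 and Spp1. State 1 was led by interferon genes, state 4 by Mmp12 and Ms4a7, and state 6 by Ly6c2 and MHC class II genes. State 2 was led by haemoglobin genes and Ttr and state 3 by ribosomal genes, Cxcl13 and S100a9, and these stay unnamed. In AD 1, state 2 held 61628 CPM of choroid plexus markers, against at most 1612 in the other libraries, and in ADAM 2 it held 169838 CPM of haemoglobin genes, against 0. Without state 2, edgeR called 8 genes in microglia instead of 5, an alternative chosen after seeing the data.

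In state 0, DAM genes stood higher in ADAM and homeostatic genes lower. The DAM list had a median log2 fold of 0.26, with 29 of 31 members positive, 0 past the test over all genes and 3 higher adjusted over the list alone (camera adjusted p = 8.7e-09, and adjusted p = 0.292 with an estimated correlation). The homeostatic list had a median of −0.13 with 0 of 20 members positive (camera adjusted p = 9.7e-04, and adjusted p = 0.693 with an estimated correlation). Glycolysis (0.27, 5 higher adjusted over the list alone), mitochondrial (0.30), lysosome (0.12) and interferon genes (0.22) also passed camera, with adjusted p of 4.5e-08, 1.8e-04, 5.6e-05 and 1.8e-04, and adjusted p of 0.584, 0.292, 0.292 and 0.693 with an estimated correlation. The same held for MHC class I (0.13, camera adjusted p = 0.019), proliferation (0.23, 0.012) and inflammatory genes (0.18, 0.031), all with adjusted p = 0.693 under an estimated correlation, and the inflammatory median was −0.13 without ADAM 2. The interferon median was −0.073 without ADAM 2, and the DAM median 0.43 without ADAM 1. The homeostatic and interferon lists did not pass camera without AD 1 (camera adjusted p = 0.061 and 0.27) or ADAM 2 (0.34 and 0.88), MHC class I and proliferation without AD 2 (0.62 and 0.88) or ADAM 1 (0.55 for both), and inflammatory genes without AD 1 (0.054) or AD 2 (0.22). By gene, edgeR called 4 higher and 7 lower of 10912 tested, with 460 at an unadjusted p under 0.05. Spint1, Gatm, Kcnip3, Eif3j1, Eif3j2 and Axl were among these, with Gatm at a log2 fold of 3.01 (SE 0.14, edgeR adjusted p = 1.5e-07). Mymk, known from muscle cell fusion, rose by 0.75 on the log2 scale (SE 0.12, edgeR adjusted p = 0.045), a call lost without AD 1 or AD 2. Without AD 1, AD 2, ADAM 1 or ADAM 2 the counts were 6, 7, 174 and 37, of which 2, 2, 143 and 17 were higher.

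In state 5, genes of the immediate early and inflammatory lists rose in ADAM, and DAM and lipid genes stood lower. Socs3, a feedback inhibitor of cytokine signalling, rose from 71.3 ± 8.45 to 134 ± 9.49 CPM (log2 0.92, SE 0.12, edgeR adjusted p = 0.0038), and the transcription factor Egr1 from 113 ± 3.46 to 210 ± 49.2 (0.90, SE 0.14, edgeR adjusted p = 0.036). The cytokine Il1b rose from 25.8 ± 7.99 to 53.3 ± 0.33 CPM (1.09, SE 0.17, edgeR adjusted p = 0.035) and Ccl12 from 41.4 ± 4.45 to 70.8 ± 3.78 (0.79, SE 0.13, edgeR adjusted p = 0.025). Pcna fell from 33.2 ± 2.96 to 13.9 ± 1.23 CPM (−1.25, SE 0.16, edgeR adjusted p = 0.0030), and Casp4, an inflammatory caspase, from 15.6 ± 0.38 to 5.56 ± 1.5 (−1.46, SE 0.23, edgeR adjusted p = 0.023). Il1b (129364570 to 129371139) and Pcna (132249162 to 132253314) lie on chromosome 2 within 20 Mb of Mertk. The pseudogene copy Pcna-ps2 (chromosome 19, 9283380 to 9284160), chosen after its values were seen, rose from 0.46 ± 0.43 to 4.59 ± 0.17 CPM (3.45, SE 0.60, edgeR adjusted p = 0.036), and the value of Pcna is uncertain where reads can be shared with it. The immediate early list had a median of 0.45 with 27 of 28 positive, 2 higher over all genes and 11 adjusted over the list alone (camera adjusted p = 2.4e-17, and adjusted p = 0.388 with an estimated correlation). For the inflammatory list these were 0.47, 18 of 23, 2 and 6 (camera adjusted p = 1.3e-10, and adjusted p = 0.402 with an estimated correlation).

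Cholesterol and lipid genes in state 5 had a median of −0.30, with 24 of 26 negative, 0 past the test over all genes and 9 lower adjusted over the list alone (camera adjusted p = 3.6e-11). DAM genes had −0.16, with 27 of 31 negative, 0 over all genes and 2 lower adjusted over the list alone (camera adjusted p = 9.4e-07). Both had an adjusted p of 0.388 with an estimated correlation. Lysosome (−0.11, camera adjusted p = 2.9e-04), interferon (0.17, 4.0e-04), MHC class II (−0.22, 0.036) and glycolysis genes (0.072, 0.044) passed camera too, with adjusted p of 0.445, 0.445, 0.531 and 0.648 under an estimated correlation. Without ADAM 2 the immediate early median was 0.17 and the inflammatory median 0.24, and neither interferon (camera adjusted p = 0.19) nor MHC class II genes (0.34) passed. MHC class II also did not pass without AD 1 (0.83), where the lysosome median was −0.043, nor glycolysis without AD 2 (0.50) or ADAM 1 (0.59). In all, edgeR called 10 genes higher and 6 lower of 10436, with 553 at an unadjusted p under 0.05, and 30, 66, 141 and 124 without AD 1, AD 2, ADAM 1 or ADAM 2, of which 16, 20, 107 and 57 were higher. The Ccl12 call was lost without AD 2 (edgeR adjusted p = 0.053). Neutrophil markers in state 5 summed to 821 CPM in ADAM 2 and to 146, 141 and 162 in AD 1, AD 2 and ADAM 1.

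In the smaller states, the chemokines Ccl3 and Ccl5 and the lipase Lpl were among the genes called. In state 3 the nuclear RNA Malat1 rose from 439 ± 136 to 1728 ± 243 CPM, the chemokine Ccl3 fell from 942 ± 266 to 363 ± 72.9 and the lipase Lpl from 420 ± 140 to 139 ± 67.0, with edgeR adjusted p of 3.6e-08, 1.5e-04 and 0.018. In state 4 the T cell chemokine Ccl5 rose from 176 ± 70.2 to 609 ± 30.7 CPM (edgeR adjusted p = 0.0018) and the interleukin 1 receptor antagonist Il1rn fell from 101 ± 50.9 to 16.4 ± 8.28 (edgeR adjusted p = 0.022), a call lost without AD 2 (edgeR adjusted p = 0.99). State 2 had Gatm higher and Spint1 at least 18.3-fold lower. The counts called by edgeR were 4 higher and 6 lower of 3191 genes in state 3, 3 and 2 of 3938 in state 4, and 1 and 1 of 3150 in state 2, with 158, 132 and 96 at an unadjusted p under 0.05. Without each of AD 1, AD 2, ADAM 1 and ADAM 2 in turn the totals were 11, 13, 20 and 13 in state 3, 21, 15, 33 and 27 in state 4, and 6, 41, 48 and 2 in state 2. Those higher in ADAM numbered 5, 4, 15 and 5 in state 3, 7, 9, 23 and 8 in state 4, and 5, 5, 46 and 2 in state 2. Among lists, the immediate early genes in state 3 (0.33, camera adjusted p = 3.6e-04) and state 4 (0.42, 2.5e-05) and MHC class II in state 4 (−0.82, 6.2e-05) passed camera, with adjusted p of 0.563, 0.566 and 0.566 under an estimated correlation. In state 2, DAM genes (−0.38, camera adjusted p = 3.6e-06) and inflammatory genes (0.67, 4.6e-04) passed, with adjusted p of 0.714 under an estimated correlation. The state 2 DAM median was 0.017 without AD 1 (camera adjusted p = 0.21) and the inflammatory one 0.22 without ADAM 2. Camera did not pass in state 3 for immediate early genes without AD 2 (0.051) or ADAM 1 (0.055), nor in state 4 for MHC class II without AD 1 (0.12).

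The DAM state was then set against the homeostatic state within libraries. State 5 exceeded state 0 by a log2 fold of 7.38 in Atp6v0d2, a subunit of the lysosomal proton pump, 7.23 in Spp1, which encodes osteopontin, and 7.15 in Gpnmb (SE 0.13 for each). Tmem204, Gp9 and Bank1 were lower in state 5 by log2 folds of −4.45, −4.25 and −4.12. Axl was higher in state 5 (2.72, SE 0.09, edgeR adjusted p = 6.3e-18) and Mertk lower (−0.69, SE 0.06, edgeR adjusted p = 1.7e-09). Gas6 was higher (0.45, SE 0.13, edgeR adjusted p = 0.028), a call lost without AD 1 (edgeR adjusted p = 0.19) or ADAM 1 (0.088), and Pros1 lower (−0.23, SE 0.06, edgeR adjusted p = 0.0032). Of 11132 genes, 3238 were higher and 3185 lower in state 5. The states were drawn by the authors from these cells and genes, so the counts describe the states and are no independent test.

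By the interaction test of edgeR, the log2 fold of state 5 over state 0 was lower in ADAM for 84 genes and higher for 29 of 11132, with 988 at an unadjusted p under 0.05. Among the lower ones were 8 of 31 DAM, 3 of 11 MHC class II and 2 of 40 lysosome genes. Lgals1, which encodes galectin 1, exceeded state 0 by a log2 fold of 4.07 in AD and 2.13 in ADAM, a difference of −1.92 (SE 0.24, edgeR adjusted p = 2.2e-11). Cybb, the catalytic subunit of the phagocyte oxidase, stood at 4.10 and 2.81 (difference −1.27, SE 0.16, edgeR adjusted p = 1.3e-10). The lipid carrier Apoe stood at 3.84 and 2.83 (−1.0, SE 0.21, edgeR adjusted p = 0.0031), the scavenger receptor Msr1 at 2.54 and 0.26 (−2.27, SE 0.39, edgeR adjusted p = 1.3e-05) and the antigen presentation gene H2-Eb1 at 5.53 and 4.46 (−1.04, SE 0.18, edgeR adjusted p = 1.5e-04). Egr1 went the other way, lower in state 5 by a log2 fold of −2.57 in AD and −1.69 in ADAM (0.88, SE 0.12, edgeR adjusted p = 1.4e-08), as did Fosb (0.70, SE 0.12, edgeR adjusted p = 4.3e-06). Apoe and Fosb lie on chromosome 7 within 20 Mb of Axl. DESeq2 called 11 genes, of which 10 were shared with edgeR. Without AD 1, AD 2, ADAM 1 or ADAM 2 the counts were 53, 51, 173 and 79, with 46, 31, 81 and 41 of the 113 genes shared. The excess of lower genes turned without ADAM 2, with 45 higher and 34 lower, and stood at 13 and 40, 13 and 38, and 27 and 146 without AD 1, AD 2 and ADAM 1. The Apoe call was lost without ADAM 2 (edgeR adjusted p = 0.70), as was that of Apoc1, a lipoprotein gene beside Apoe with a difference of −2.38 (edgeR adjusted p = 0.77).

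By list, the DAM genes had a median difference of −0.48, with 8 of 31 lower over all genes (camera adjusted p = 3.5e-30). Lysosome genes had −0.24 with 2 lower (camera adjusted p = 1.2e-14), cholesterol and lipid genes −0.31 with 2 lower (1.1e-07), MHC class II −0.20 with 3 lower (9.4e-05) and phagocytosis genes −0.14 with 3 lower (3.9e-05). The DAM list shares Ctsb, Ctsd, Ctsl, Ctsz, Cd63 and Cd68 with the lysosome list and Apoe, Lpl and Fabp5 with the cholesterol list. The lysosome and cholesterol results are thus not separate from that of the DAM list. Immediate early genes had a median of 0.33 with 6 of 28 higher (camera adjusted p = 3.8e-11), and homeostatic genes 0.17 with 0 past the test (1.3e-04). With an estimated correlation the adjusted p was 0.208 for the DAM, lysosome, cholesterol, MHC class II and homeostatic lists, 0.361 for phagocytosis and 0.302 for the immediate early list. The interferon list did not pass (−0.097, camera adjusted p = 0.195). The DAM median was −0.40, −0.52, −0.58 and −0.30 without AD 1, AD 2, ADAM 1 and ADAM 2, with 4, 6, 11 and 2 members lower. The immediate early median was 0.37, 0.24, 0.16 and 0.55 in the same order, with 2, 1, 2 and 8 members higher and 0, 1, 1 and 0 lower. Lower lysosome genes numbered 0, 1, 4 and 0, phagocytosis genes 1, 0, 3 and 0 and cholesterol genes 2, 2, 2 and 0. The MHC class II median was −0.091 without AD 1, the phagocytosis median −0.054 without ADAM 2 and the homeostatic median 0.10 without AD 2.

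**Figure D3:**
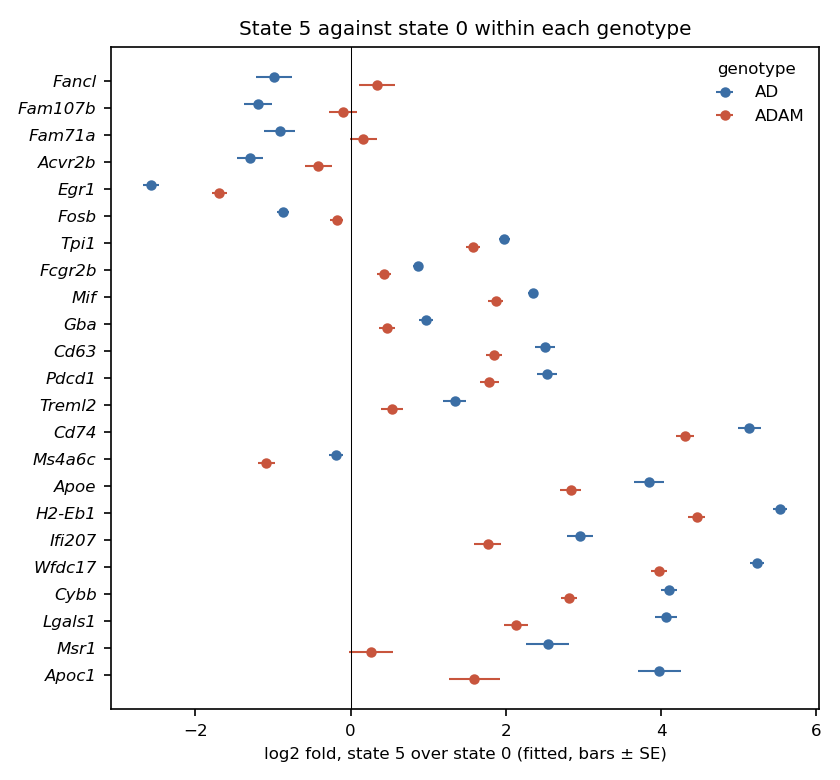
Log2 fold of state 5 over state 0 within AD and within ADAM (fitted, bars ± SE) for the named genes of the interaction test. Lgals1 falls from 4.07 in AD to 2.13 in ADAM and Egr1 lies nearer to 0 in ADAM.

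Among the other immune cells, monocytes differed most clearly in interferon genes, which were lower in ADAM. Ifi206, a sensor of the PYHIN family, fell from 66.9 ± 3.1 to 6.82 ± 2.05 CPM (log2 −3.35, SE 0.34), Ifit2, which inhibits viral translation, from 51.9 ± 7.63 to 6.32 ± 0.17 (−3.01, SE 0.34), and Rtp4 from 184 ± 40.5 to 33.2 ± 0.14 (−2.46, SE 0.26), each with an edgeR adjusted p of 0.039. The matrix protease Mmp14 rose from 3.71 ± 0.48 to 52.2 ± 5.11 CPM (3.79, SE 0.42) and Marcksl1, which binds actin, from 28.3 ± 2.86 to 130 ± 11.1 (2.18, SE 0.26), at the same edgeR adjusted p. The interferon list had a median of −1.60, with 0 of 28 positive, 4 lower over all genes and 25 lower adjusted over the list alone (camera adjusted p = 1.7e-49, and adjusted p = 0.260 with an estimated correlation). MHC class I (−0.76, 7 lower adjusted over the list alone, camera adjusted p = 1.1e-10) and class II (−1.98, 3 lower adjusted over the list alone, 1.6e-06) were lower too, with an adjusted p of 0.458 under an estimated correlation. Beside these lists, monocyte markers stood at 14886, 13798, 7827 and 12507 CPM in AD 1, AD 2, ADAM 1 and ADAM 2, dendritic cell markers at 69.3, 79.5, 41.6 and 30.3, and B cell markers at 162, 193, 91.8 and 23.6. The class II median was −1.28 without AD 1, −3.07 without ADAM 1 and −1.26 without ADAM 2. Inflammatory (0.68, camera adjusted p = 3.0e-04) and glycolysis genes (0.45, 0.0023) were higher, with adjusted p of 0.375 and 0.50 under an estimated correlation, and the inflammatory list did not pass without ADAM 2 (camera adjusted p = 0.15) nor glycolysis without AD 2 or ADAM 2 (0.10 for both).

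For monocytes edgeR called 3 genes higher and 7 lower of 6460, with 550 at an unadjusted p under 0.05. DESeq2 called 52 and limma-voom 0, with 551 at an unadjusted p under 0.05. Without AD 1 or AD 2 edgeR called 0 (310 and 612 at an unadjusted p under 0.05), and without ADAM 1 or ADAM 2 it called 274 and 86, of which 152 and 33 were higher. Neutrophil markers made up 119, 2109, 4220 and 70519 CPM of the monocyte libraries AD 1, AD 2, ADAM 1 and ADAM 2. Among monocytes with under 1% of UMIs from these markers, 135 genes were called and 23 interferon genes were lower adjusted over the list alone, an alternative chosen after seeing the data.

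**Figure D4:**
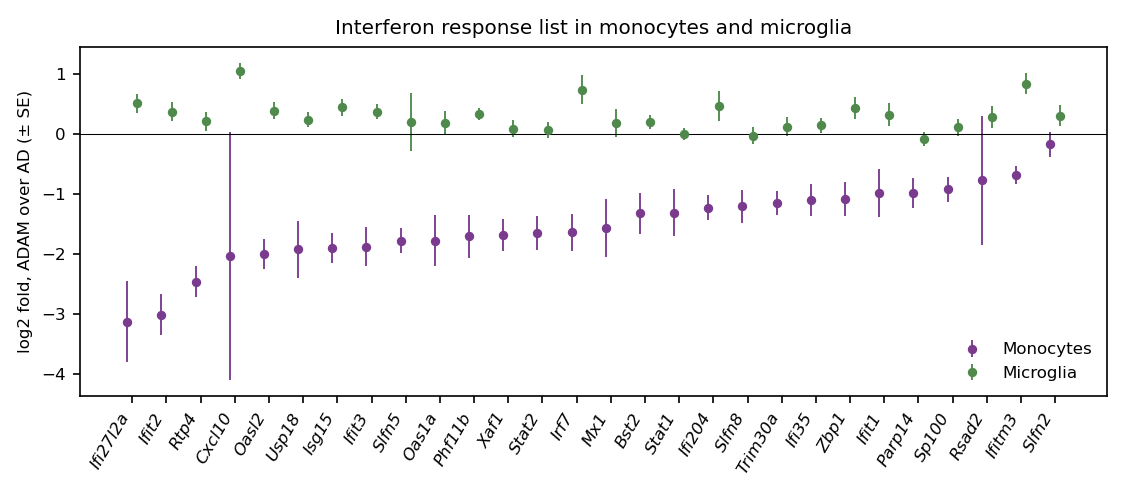
Log2 fold, ADAM over AD (± SE), of each interferon response gene in monocytes and in microglia. All 28 monocyte values lie below 0, with a median of −1.60, and the microglial median is 0.23.

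T and NK cells of ADAM held more transcripts of genes known from microglia and myeloid cells. Lyz2, which encodes lysozyme, rose from 38.2 ± 2.67 to 117 ± 12.9 CPM (log2 1.61, SE 0.14, edgeR adjusted p = 3.0e-04), the complement gene C1qb from 159 ± 5.52 to 334 ± 51.4 (1.06, SE 0.14, edgeR adjusted p = 0.0054) and the microglial receptor Trem2 by 0.84 on the log2 scale (SE 0.14, edgeR adjusted p = 0.025). The nucleoside transporter Slc28a2, which lies within 20 Mb of Mertk, fell (−1.93, SE 0.27, edgeR adjusted p = 0.0086). The phagocytosis and complement list had a median of 0.68, with 4 higher over all genes and 9 adjusted over the list alone (camera adjusted p = 3.2e-12, and adjusted p = 0.241 with an estimated correlation). The DAM list had 0.24, with 4 and 7 higher (camera adjusted p = 2.4e-12, and adjusted p = 0.210 with an estimated correlation), and the homeostatic microglia list 0.55, with 0 and 6 higher (camera adjusted p = 7.2e-08, and adjusted p = 0.370 with an estimated correlation). Microglia markers in these cells summed to 597, 612, 1132 and 817 CPM in AD 1, AD 2, ADAM 1 and ADAM 2, and neutrophil markers to 1733 in ADAM 2 against at most 42.1 elsewhere. In all, edgeR called 18 genes higher and 5 lower of 9533, with 496 at an unadjusted p under 0.05, and limma-voom called 4. Without AD 1 the count was 4, without AD 2 19, without ADAM 1 33 and without ADAM 2 37, of which 2, 7, 29 and 31 were higher, and the calls of C1qb and Trem2 were lost without AD 1 (edgeR adjusted p = 0.12 and 0.44). The homeostatic median was 0.26 without ADAM 1 and the DAM median 0.43 without ADAM 2.

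In macrophages Axl was the 1 gene called by edgeR of 6483, with 143 at an unadjusted p under 0.05. Without AD 1, AD 2, ADAM 1 or ADAM 2 it called 4, 4, 130 and 20, of which 2, 0, 111 and 5 were higher, while DESeq2 called 2 and limma-voom 0 (156 at an unadjusted p under 0.05). Their homeostatic (−0.33, camera adjusted p = 7.8e-06), interferon (−0.25, 0.0062) and glycolysis lists (0.33, 0.0071) had an adjusted p of 0.834 under an estimated correlation. Camera did not pass for any of them without ADAM 2 (camera adjusted p = 0.32, 0.71 and 0.32), for homeostatic and glycolysis genes without AD 2 (0.96 for both), for interferon genes without AD 1 (0.44) and for glycolysis without ADAM 1 (0.13), and the interferon median was 0.027 without ADAM 2. In proliferating cells Igkc, the kappa light chain, and Cd79a, a subunit of the B cell receptor within 20 Mb of Axl, were lower in ADAM, with Igkc at 474 ± 203 CPM in AD and 3.34 ± 3.08 in ADAM (log2 −7.12, SE 0.66, edgeR adjusted p = 0.020) and Cd79a at least 70.5-fold lower. B cell markers in these cells stood at 323, 800, 101 and 48.9 CPM in AD 1, AD 2, ADAM 1 and ADAM 2. Saa3, an acute phase gene, was 404-fold higher (counting interval 72.3 to 15967, edgeR adjusted p = 0.035). These cells held 5629, 3000, 1363 and 630 CPM of T cell markers and 48.1, 215, 158 and 18517 CPM of neutrophil markers in AD 1, AD 2, ADAM 1 and ADAM 2. Of 7124 genes, 2 were higher and 4 lower, with 622 at an unadjusted p under 0.05, and DESeq2 called 67 and limma-voom 0 (533). The count was 30 without AD 1, 12 without AD 2, 750 without ADAM 1 and 778 without ADAM 2, of which 6, 2, 373 and 503 were higher.

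The makeup of the sorted cells was compared last, as shares of cells with a class. Endothelial cells were higher in ADAM, with 0.0941% ± 0.0034 in AD and 0.455% ± 0.142 in ADAM (log2 fold 2.24, SE 0.52, edgeR adjusted p = 0.047), from 3 and 4 cells against 12 and 21. This call was lost without any single library, with edgeR adjusted p of 0.282, 0.193, 0.073 and 0.317 without AD 1, AD 2, ADAM 1 and ADAM 2, and CD45 sorting should remove this cell type. Microglia made up 64.7% ± 9.13 of AD and 61.6% ± 9.80 of ADAM cells, T and NK cells 25.9% ± 9.84 and 19.8% ± 0.378, and monocytes 2.66% ± 0.385 and 5.10% ± 1.02 (edgeR adjusted p = 0.211), none past the test. The microglia share includes cells that the authors marked as microglia and T cell doublets, 209 of 1809 in AD 1, 3 in AD 2, 0 in ADAM 1 and 4 in ADAM 2. Neutrophils made up 0.966%, 3.12%, 0.325% and 15.4% of AD 1, AD 2, ADAM 1 and ADAM 2 (exact 95% intervals 0.652 to 1.38, 2.62 to 3.68, 0.163 to 0.581 and 14.2 to 16.5), with a log2 fold of 1.94 (edgeR adjusted p = 0.442). Neutrophils were called without ADAM 1 (log2 fold 2.90, edgeR adjusted p = 0.011), and the fold was −2.65 without ADAM 2 (edgeR adjusted p = 0.093).

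Within microglia 0 of 7 state shares passed in edgeR, with 0 at an unadjusted p under 0.05. State 0 held 56.3% ± 11.9 of AD and 46.8% ± 9.75 of ADAM microglia (edgeR adjusted p = 0.845), state 5 30.2% ± 9.78 and 32.3% ± 7.21 (0.877), and state 2 5.02% ± 0.202 and 10.5% ± 1.97 (0.845). State 6 was called without AD 1 alone (edgeR adjusted p = 0.030). DAM list transcripts per cell averaged 145.8 ± 24.8 UMIs per 2000 in AD and 148.6 ± 23.5 in ADAM, where the exact permutation p was 0.667. The share of cells above the 75th percentile of AD cells was 26.9% ± 8.59 in AD and 23.8% ± 8.58 in ADAM, and 8.61% of cells lay within 10% of that level. Neither direction held, since the share above the 50th percentile was 51.8% ± 9.53 in AD and 63.8% ± 11.5 in ADAM, the difference at the 75th was +2.98 percentage points without AD 1 and −9.16 without AD 2, and the mean level differed by +20.4 UMIs without AD 1 and by −14.7 without AD 2.

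**Figure D5:**
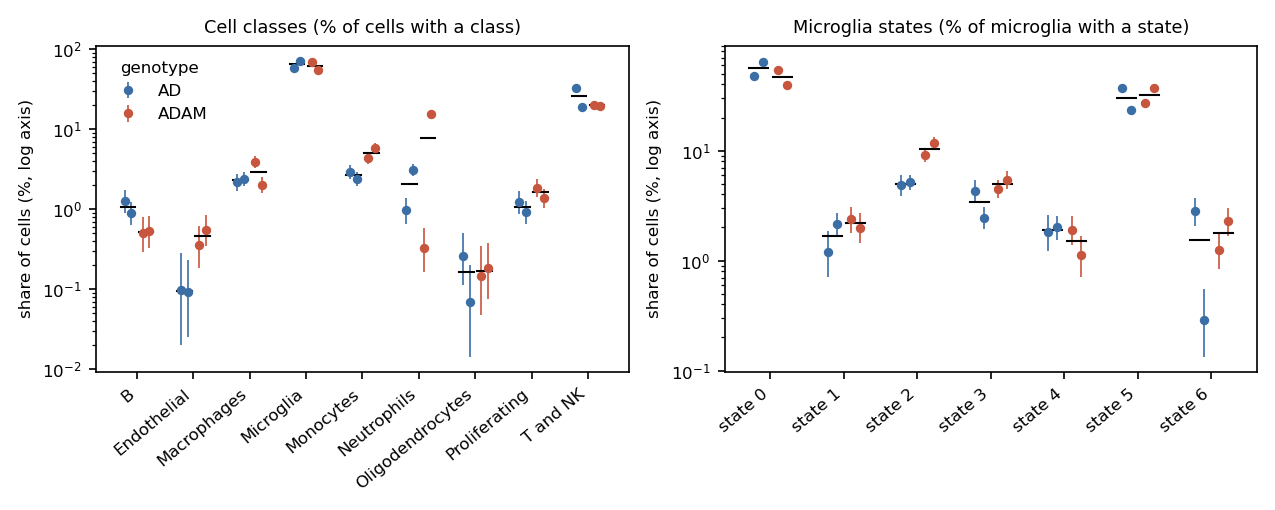
Share of cells (%, log axis) per library with exact 95% intervals, for classes among cells with a class and for states among microglia, with means as lines. Neutrophils reach 15.4% in ADAM 2 and lie at 3.12% or below in the other libraries.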

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

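The comparison by gene position was set before the data were examined, but its reading as a test of explanations was chosen only after the result was seen. The tests of the summed Eif3j copies, of free RNA, of leaving out ADAM 2 and of genes outside chromosome 1 were also chosen after it. So were both comparisons of other cell classes with microglia. The tests across cell types, with own clusters and in monocytes poor in neutrophil transcripts were set before their results were known, although the last 2 use cell selections added after seeing the data.

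The genotype difference was not the same in state 5 and state 0 microglia, by the interaction test of edgeR, for 113 genes, with DAM genes gaining less from state 0 to state 5 in ADAM (median difference −0.48, camera adjusted p = 3.5e-30, and adjusted p = 0.208 with an estimated correlation). The border drawn by the authors stays open, since own clusters, with a median of −0.50 (SE 0.082), put 119 of 7554 cells on the other side of it and so hardly moved it. Free RNA of DAM transcripts stays open as well, since the list gained 0.349 times as many CPM in T and NK cells as in state 0 of ADAM 1 and 0.094 times as many in ADAM 2. The list already stood at 10291 and 9726 CPM in the T and NK cells of AD 1 and AD 2. Whether its gain there was free RNA or came from the T and NK cells themselves was not tested, so the ratio cannot decide. The ADAM 2 library with its neutrophil RNA stays open too, since without it the median was −0.30, beyond the bound of −0.2 by less than the SD of 0.126 among the medians without each library. The genotype itself may also lie behind the pattern, and these data do not separate it from the open explanations.

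Monocytes and microglia differed in their genotype effect for 45 genes by the interaction test of edgeR, 15 higher and 30 lower in monocytes of 11416, with 846 at an unadjusted p under 0.05. The difference of log2 folds was −3.34 for Ifit2 (SE 0.44), −2.59 for Rtp4 (SE 0.31) and −2.36 for Irf7, the master regulator of type I interferon (SE 0.38), with edgeR adjusted p of 0.0021, 7.6e-04 and 0.034. Mmp14 stood at +3.87 (SE 0.53) and Ifitm1 at +3.22 (SE 0.36), while Ttr, a choroid plexus gene, stood at +6.70 (SE 0.71) and choroid plexus markers at 693 CPM in AD 1 microglia against at most 69.6 elsewhere. The interferon list had a median difference of −1.68 with 11 of 30 members lower (camera adjusted p = 6.5e-23, and adjusted p = 0.395 with an estimated correlation). The count was 31 without AD 1, 103 without AD 2, 239 without ADAM 1 and 139 without ADAM 2, of which 7, 54, 91 and 69 were higher.

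For the lower interferon genes in ADAM monocytes, monocytes with under 1% of UMIs from neutrophil markers (91, 100, 145 and 101 cells in AD 1, AD 2, ADAM 1 and ADAM 2) had a median log2 fold of −1.54 (SE 0.18). This argues against neutrophil-like cells in the class as the whole cause. The median was −1.43 without ADAM 2 (SE 0.16), which argues against that library alone. It was −1.65 over the 25 of 28 members outside chromosome 1 (SE 0.17), so the fall was not confined to that chromosome. For these 25 members, that argues against strain variants that change only the interferon-inducible cluster of chromosome 1. Leaving out so few members could hardly move the median past the bound. Such variants are therefore not excluded for the members on chromosome 1, and whether they act on genes elsewhere was not tested. The makeup of the class stays open, since monocyte markers stood at 14886 and 13798 CPM in AD and 7827 and 12507 in ADAM, dendritic cell markers at 69.3 and 79.5 against 41.6 and 30.3 and B cell markers at 162 and 193 against 91.8 and 23.6. A weaker interferon program may also lie behind the pattern, a hypothesis that these data do not separate from the makeup of the class or from other differences between the pools.

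T and NK cells and microglia differed in their genotype effect for 23 genes by edgeR, 19 higher and 4 lower in T and NK cells of 11880, with 629 at an unadjusted p under 0.05. The difference of log2 folds was +2.69 for Sqor (SE 0.40), +1.96 for S100a8 (SE 0.25), +1.73 for Lyz2 (SE 0.19) and +1.05 for C1qb (SE 0.14), with edgeR adjusted p of 8.9e-04, 1.7e-04, 4.2e-05 and 2.2e-04. Sqor lies within 20 Mb of Mertk, and S100a8 and S100a9 summed to 9.89, 32.6, 18.1 and 1542 CPM in the T and NK cells of AD 1, AD 2, ADAM 1 and ADAM 2. Ttr stood at +8.35 (SE 0.39) and Prr5l at −1.59 (SE 0.33). The homeostatic list had a median difference of 0.69 (camera adjusted p = 2.6e-11, and adjusted p = 0.307 with an estimated correlation). The count was 64 without AD 1, 88 without AD 2, 27 without ADAM 1 and 25 without ADAM 2, of which 25, 61, 16 and 23 were higher.

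Genes called in microglia gathered near Mertk, with an odds ratio of 80.6 (7.97 to 3871) that rests on 4 calls. These calls make up the pattern, so this ratio restates it and does not decide for linked strain sequence. At an unadjusted p under 0.05, 8.30% of near genes and 2.04% of others differed in microglia (odds ratio 4.34, 3.06 to 6.04). That argues against loss of receptor function acting without regard to position as the whole cause in microglia. The same ratio was 3.61 in state 0 (2.69 to 4.79), 2.22 in state 5 (1.60 to 3.03) and 1.52 in T and NK cells (1.02 to 2.20). It was 1.79 in macrophages and 2.09, 1.39 and 1.96 in states 2, 3 and 4, with intervals that reached below 1. In monocytes and proliferating cells it was 1.06 (0.668 to 1.62) and 1.02 (0.655 to 1.53). Eif3j1 and Eif3j2 summed to 117 ± 12.8 CPM in AD and 68.4 ± 12.03 in ADAM, a log2 ratio of −0.78, which argues against reads that moved from 1 copy to the other without loss. Reads can be shared between the copies, so a move with loss of reads stays open. In T and NK cells 18 of 34 near genes kept the sign they had in state 0 (52.9%), against 167 of 276 genes elsewhere (60.5%), an odds ratio of 0.735 (0.338 to 1.61, Fisher's exact p = 0.46) that leaves undecided whether a linked effect is seen across cell types. Genes called there were 5 of 439 tested within 20 Mb of Axl or Mertk and 18 of 9092 elsewhere. The odds ratio was 5.81 (1.68 to 16.3, Fisher's exact p = 0.0034), with 4 of the near calls by Mertk and 1 by Axl. These calls are part of the pattern too, and that of Gatm is not shown to be independent of microglia, so this ratio does not decide either. Linked strain sequence and an effect of receptor loss on some of these genes both stay open.

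Cells that the authors marked as doublets without a class entered no comparison of classes or genes, and no test of their transcripts was run. They numbered 134 in AD 1, 181 in AD 2, 196 in ADAM 1 and 312 in ADAM 2, or 4.13%, 3.98%, 5.48% and 7.63% of cells. In the microglia class, whose share of cells includes them, the authors marked 209 cells of AD 1 as microglia and T cell doublets, 11.6% of that class, against 3 in AD 2, 0 in ADAM 1 and 4 in ADAM 2.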

How the results depend on the processing

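Of the tests below, those with low-neutrophil monocytes, own clusters in the interaction, without state 2, with the microglia and T cell doublets and with crossed replicate numbers were chosen only after the result was seen. Each share, called list or named gene was counted once per alternative, so the numbers that follow are values and not items. For class and state shares, 107 values kept their direction and side of the threshold, 7 lost the call, 2 gained it and 16 turned direction. For shares and named genes, the values kept include results that were called neither before nor after. For gene lists these were 371, 144, 0 and 10, and for named genes 2250, 204, 143 and 20. Of the 144 list values that lost the call, 70 came from the estimated correlation. That form ended every list call and called 0 of 10 planted lists on simulated counts, so its losses do not separate firm lists from fragile ones. The comparison of state 5 with state 0 called between 5606 and 6754 genes under every alternative run. RLE size factors moved no count of genes past 1.5 times. Where a cause is not given below, the cause was not tested.

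Without the low-count filter edgeR called 18 genes in microglia instead of 5, 11 in macrophages instead of 1, 276 in monocytes instead of 10, 340 in proliferating cells instead of 6 and 107 in T and NK cells instead of 23. In the states it called 94 in state 0 instead of 11, 12 in state 2 instead of 2, 16 in state 4 instead of 5 and 112 in state 5 instead of 16. With at least 100 counts in all, where fewer genes are tested, edgeR called 2 genes in macrophages, 3 in state 3, 3 in state 4 and 0 in monocytes, proliferating cells and state 2, with 391, 340 and 25 at an unadjusted p under 0.05.

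DESeq2 called 17 genes in microglia, 2 in macrophages, 52 in monocytes, 67 in proliferating cells, 1 in state 2, 5 in state 3, 3 in state 4 and 11 in the interaction. In microglia its log2 fold of Axl was −3.71 and passed (DESeq2 adjusted p = 2.5e-37). Limma-voom called 4 genes in T and NK cells, 7 in state 0, 5 in state 3 and 2 in state 4, and 0 in macrophages, monocytes, proliferating cells and state 2, with 156, 551, 533 and 111 at an unadjusted p under 0.05. Its log2 fold of Axl in microglia was −3.71 (limma adjusted p = 0.022), and that of Mertk in proliferating cells turned to −0.047. Over the alternatives for Axl in microglia the adjusted p ran from 2.5e-37 to 0.874.

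Other selections of microglia moved the count of called genes to 8 without state 2, 26 under a marker rule and 16 with equal cells per state, with log2 folds of Axl at −5.02 under the marker rule and −3.87 with equal cells per state, both past the test. Without genes within 20 Mb of Axl or Mertk edgeR called 0 (230 at an unadjusted p under 0.05). This alternative takes out 4 of the 5 called genes, and Eif3j2 on chromosome 18, which stays in, also lost its call. Under the marker rule, which kept 351, 403, 410 and 21 cells of AD 1, AD 2, ADAM 1 and ADAM 2, H2-D1 (−0.027), Scd2 (0.0027), Treml2 (−1.11), Rgs1 (−0.18), the interferon list (−0.086) and the immediate early list (−0.19) turned direction. With the microglia and T cell doublets included, Ccl5 turned to −0.13. Low-neutrophil monocytes gave 135 called genes, and own clusters gave 69 in the interaction.

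For shares, TMM over classes or states called 0 classes instead of 1 and turned microglia to 0.021, state 1 to −0.024, state 5 to −0.28 and state 6 to −0.11. The exact permutation test also called 0 classes, as it cannot pass the threshold with 2 libraries per genotype. For state 5 the DAM-like cells of the own clustering stood in, which turned the share to −0.26 at resolution 0.6, where they held 1367 state 5 cells, and gave 0.085 and 0.12 at resolutions 0.3 and 1.0, where they held 2621 and 2574. For lists, camera with an estimated correlation called 0 in microglia instead of 6 and 0 in the other sets instead of 52, and fry called 0 in microglia for directional and 0 for mixed changes, with 0 and 1 at an unadjusted p under 0.05. Windows of 10 and 5 Mb around Axl and Mertk had odds ratios of 116.7 and 12.7, the second no longer past the test, as it holds 1 of the 4 called genes. The DAM list per cell turned to −0.0088 as percent of UMIs without thinning, and the share of cells above the 50th percentile to +12.0021 percentage points.

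Leaving out each library in turn gave ranges from lowest to highest, with fewer samples in each fit. Called genes ran from 12 to 139 in microglia, 4 to 130 in macrophages, 0 to 274 in monocytes, 12 to 778 in proliferating cells, 4 to 37 in T and NK cells and 51 to 173 in the interaction. In the states they ran from 6 to 174 in state 0, 2 to 48 in state 2, 11 to 20 in state 3, 15 to 33 in state 4 and 30 to 141 in state 5. The 0 in monocytes came from edgeR without AD 1 and without AD 2, with 310 and 612 at an unadjusted p under 0.05. Called classes ran from 0 to 1, which was neutrophils without ADAM 1, and called states from 0 to 1. Log2 folds of shares ran from −0.18 to 0.76 in macrophages, −0.24 to 0.083 in microglia, −2.65 to 3.02 in neutrophils, −0.62 to 1.24 in oligodendrocytes and −0.73 to 0.059 in T and NK cells. State 5 ran from −0.20 to 0.47 and state 6 from −0.68 to 2.58. Lists called in microglia ran from 4 to 11. The DAM level per cell differed by −14.7 to 20.4 UMIs and the share above the 75th percentile by −9.16 to 2.98 percentage points.

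For genes in microglia the folds ran from −4.01 to −3.35 for Axl, past the test without AD 1 or AD 2, −0.19 to 0.030 for Mertk, −0.038 to 0.13 for Pros1, −0.013 to 0.38 for Ctsl and −0.036 to 0.66 for Rgs1. Mertk ran from −0.76 to 0.62 in macrophages, −0.77 to 0.65 in proliferating cells, −0.17 to 0.11 in state 0, −0.43 to 0.44 in state 4, −0.39 to 0.14 in state 5 and −0.215 to 0.020 in the interaction. List medians in microglia ran from −0.34 to 0.043 for homeostatic, −0.047 to 0.40 for inflammatory and −0.081 to 0.32 for immediate early genes. Lysosome genes in proliferating cells ran from −0.13 to 0.92, inflammatory genes from −0.13 to 0.47 in state 0 and −0.19 to 0.45 in state 4, glycolysis genes in state 5 from −0.069 to 0.16, and interferon genes in state 4 from 0.050 to 0.91, where the direction of the test turned.

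The libraries share only a replicate number. The deviations of the same-numbered libraries correlated at −0.22 in microglia, −0.13 in macrophages, 0.051 in monocytes, −0.0042 in proliferating cells and 0.080 in T and NK cells. In states 0, 2, 3, 4 and 5 they correlated at 0.096, −0.28, 0.070, 0.11 and 0.064. With the replicate number as a block edgeR called 0 genes in microglia (234 at an unadjusted p under 0.05), 3 in monocytes (3 higher and 0 lower, with 0 of the 10 genes shared, so that the calls of Ifi206, Ifit2 and Rtp4 ended), 80 in proliferating cells, 90 in T and NK cells, 35 in state 0, 6 in state 2, 21 in state 3 and 3 in state 4. It called 0 classes, and Mertk turned to −0.020 in proliferating cells and −0.073 in state 4. With crossed replicate numbers as the block, chosen after seeing the data, edgeR called 8 genes in microglia, 9 in macrophages and 0 in state 2 (108 at an unadjusted p under 0.05), with Axl at −3.69 in microglia.

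Depth alone did not set what could be called. On simulated counts, 78% of 4-fold changes were recovered in state 4, with 180002 to 611143 UMIs per library and a common dispersion of 0.030, and 0% in proliferating cells, with 291361 to 940781 UMIs and a dispersion of 0.112. The share was 41% in state 2 (96012 to 343004 UMIs) and 45% in monocytes, so a gene not called there is not shown to be unchanged.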

Other observations

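The list tests below were set before the data were examined, while the sums of S100a8 and S100a9, Saa3 and the cluster they lead were chosen only after the result was seen. In proliferating cells, DAM genes stood higher in ADAM and homeostatic, cell cycle and T cell genes lower. DAM genes had a median log2 fold of 0.74 with 21 of 26 positive, 0 past the test over all genes and 6 higher adjusted over the list alone (camera adjusted p = 1.4e-05). Spp1 was at 50.2 ± 17.5 CPM in AD and 388 ± 332 in ADAM (edgeR adjusted p = 0.22). Homeostatic genes had −0.98 with 0 of 20 positive (camera adjusted p = 1.9e-07), and proliferation genes −0.50 with 1 of 25 positive (camera adjusted p = 1.4e-05). T cell activation genes had −0.99, with 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 9.9e-05). Among these, Gzmk, a granzyme of memory T cells, was at 148 ± 29.3 and 31.8 ± 3.85 CPM, and the adhesion receptor Cd44 at 27.7 ± 5.08 and 200 ± 30.4, with edgeR adjusted p of 0.104 and 0.0539. Lysosome (0.46, camera adjusted p = 0.0012), glycolysis (0.48, 0.0034) and MHC class I genes (−0.51, 0.014) passed camera too. With an estimated correlation the adjusted p was 0.846 or above for all 7 lists, up to 0.917 for lysosome and proliferation. Without ADAM 1 the lysosome median was −0.13, the DAM median 0.088 and the proliferation median −0.067 (camera adjusted p = 0.46, 0.049 and 0.25). The homeostatic list did not pass without ADAM 2 (camera adjusted p = 0.053), and neither did MHC class I without AD 1 (0.24) or ADAM 2 (0.075). T cell markers in these cells stood at 5629 and 3000 CPM in AD 1 and AD 2 and at 1363 and 630 in ADAM 1 and ADAM 2, and neutrophil markers at 18517 CPM in ADAM 2.

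Other lists also passed camera outside the sets described so far. In T and NK cells MHC class II (0.70, camera adjusted p = 1.9e-05), lysosome (0.20, 2.3e-08) and inflammatory genes (0.20, 4.1e-05) were higher in ADAM, with adjusted p of 0.246, 0.246 and 0.241 under an estimated correlation. In state 2, cholesterol and lipid (−0.63, camera adjusted p = 4.6e-04), mitochondrial (−0.43, 0.0031) and lysosome genes (−0.29, 0.0089) were lower and glycolysis genes higher (0.31, 0.045), with an adjusted p of 0.714 under an estimated correlation. In state 3, DAM (−0.14, camera adjusted p = 0.0012) and cholesterol genes (−0.20, 0.0048) were lower, with an adjusted p of 0.563 under an estimated correlation. In state 4, DAM genes were lower (−0.092, camera adjusted p = 0.049) and interferon (0.30, 0.042) and inflammatory genes higher (0.17, 0.049), with adjusted p of 0.566, 0.697 and 0.697 under an estimated correlation. The inflammatory median in state 4 was −0.19 without AD 1. Apart from inflammatory genes in T and NK cells and lysosome genes there, which passed camera without each library, all of these lists lost the call without at least 1 library.

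The neutrophil transcripts S100a8 and S100a9 set ADAM 2 apart in microglia, T and NK cells and macrophages. These alarmins summed to 15.5, 46.4, 13.9 and 694 CPM in the microglia of AD 1, AD 2, ADAM 1 and ADAM 2, to 9.89, 32.6, 18.1 and 1542 in T and NK cells and to 6.53, 266 and 10.3 against 1602 in macrophages. Own clustering of microglia at resolution 0.6 held a cluster led by S100a9, S100a8, C4b, Retnlg, Tnf and Ccl12 with 12, 52, 31 and 741 cells of these libraries. Saa3 stood at 5.94, 1.69, 336 and 6041 CPM in monocytes, at 0.117, 0.415, 3.88 and 14.2 in microglia and at 0, 1.52, 6.85 and 3.82 in macrophages of AD 1, AD 2, ADAM 1 and ADAM 2.

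Mertk in T and NK cells was at 2.78 and 4.44 CPM in AD 1 and AD 2 and at 9.06 and 9.66 in ADAM 1 and ADAM 2, a log2 fold of 1.38 (SE 0.38) that did not pass (edgeR adjusted p = 0.378). The share of these cells with a Mertk UMI was 0.881% (exact 95% interval 0.403 to 1.67), 1.45% (0.751 to 2.52), 3.39% (2.16 to 5.05) and 3.39% (2.21 to 4.97), against 60.3% to 74.7% of microglia. Other genes known from microglia also stood higher in the T and NK cells of ADAM. Whether these Mertk UMIs came from microglia was not tested. In state 3, Mertk stood at 69.1 ± 14.5 CPM in AD and 24.6 ± 3.3 in ADAM, which did not pass either (log2 fold −1.53, SE 0.43, edgeR adjusted p = 0.196).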
